A study of Mus musculus with 6 samples.

How the data were processed

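Total RNA from frozen skeletal muscle of 6 mice was extracted with Trizol, purified on RNeasy columns and labelled with biotin for Affymetrix arrays, per the labels' protocols, and was hybridised to MoGene arrays, per the series' design text. The authors deposited 1 table of log2 expression values with 35557 probe sets and 1 column per array. The log2 scale was read from the values, which span 1.41 to 15.1. The summarization, background correction and normalization of the deposited log2 values are not given in the sources used here. Array medians differed by 0.0571 and interquartile ranges by 0.0617, under the limit of 0.1 set before the data were examined, so the values were used as deposited. All 6 columns belong to samples of the series and 0 columns of per-sample values were left out. The labels give 1 common date for all arrays and name no other batch. No array was a copy of another. Because raw probe intensities were not used here, signal over background could not be assessed and no dim probe set was removed from the main test.

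Arrays were grouped as transgenic (TG) or wild type (WT) by their labels, 3 in each group, and replicates were numbered in deposit order, which pairs no animals. Gene symbols came from the platform's annotation. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had none in that table, and those with several or none were not named. Each gene was represented by the probe set with the highest mean over the 6 arrays, which gave 19938 genes, 999 of them with several probe sets. Among the named genes, 7 had several probe sets, and these had the same sign in all 7 genes. Gene order came from the reference table of assembly GRCm38.p6, to which 19856 genes matched by gene identifier. By symbol, 19917 genes were placed on chromosomes for the scan of neighbouring genes. The deposited table names no genome build, so no positions are given.

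Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without trend or robust moderation, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Differences are TG minus WT on the log2 scale, intervals are at 95%, and a "±" is the SD over 3 arrays. Figures were drawn with matplotlib 3.10.9. The named genes were set by a rule fixed before the data were examined, along with the tests, the lists and all alternatives not said to be added later. The rule takes Socs3, then the 10 genes per direction with the largest difference among those past the threshold, filled up with the genes of smallest unadjusted p whose groups do not overlap, then up to 4 members of each called list and 2 of each other list by smallest p. Lists of pathways and cell type markers (40 lists, 784 genes, 723 measured) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests a list against no change and not against other genes, as alternatives. Lists with fewer than 5 measured members and the sex-linked list were not tested. Adjusted p-values of lists are over the 38 lists tested, and those adjusted over the list alone are over its members.

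The alternatives were an intensity trend, robust moderation, array weights, the genes above the median level, every probe set, the mean of a gene's probe sets, quantile normalization, a common array median, a rule of unadjusted p under 0.01 with a 1.5-fold change, each array left out in turn and, for lists, ranks of the statistic. A covariate from 15 liver transcripts, the STAT5 list without Socs2, the scan of neighbouring genes, and the lists of liver transcripts (15 genes, and 18 measured of those not looked at before) and of bone and osteoclast transcripts were added after seeing the data. The scan counted genes with an unadjusted p under 0.01 in every run of 30 neighbouring tested genes.

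The steps were tested on 20 simulated datasets of 19938 genes with 3 arrays against 3, in which 200 genes were changed. The test recovered 46.0% of genes changed by a log2 of 0.5, 87.4% at 1 and 99.3% at 2, and 4.20% of the calls were unchanged genes. These shares hold for 200 changed genes, since the adjusted threshold is stricter where fewer genes change. In the data, 10 genes had an absolute log2 difference over 1 and 1 gene passed. With nothing changed, 0 datasets gave a gene call and 1 gave a list call. When the real arrays were regrouped into the other sets of 3 against 3, every regrouping gave list calls, from 1 to 8. The simulated count therefore cannot be taken as the rate of false list calls in these data. A shift of 0.2 put on the macrophage list was called in 20 datasets with the preset correlation and in 0 with the estimated one. The scan was tested apart from these arrays, on random marks along the gene order and without a fit. It found the planted run in 20 such sets and reached at most 5 marked genes with nothing planted. The planted run held more marks than that by construction, so finding it checks the counting alone and not the power of the scan.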

Results

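Gene expression was measured in skeletal muscle of 6 mice on Affymetrix MoGene arrays, 3 from mice labelled transgenic (TG) and 3 from mice labelled wild type (WT), in a series titled for SOCS-3 in muscle. The labels name a separate subject for each array, so each array stands for 1 mouse. They give neither the muscle taken nor what the transgene carries. Each array held 35557 probe sets, of which 19938 genes were tested. Median log2 expression per array lay between 5.98 and 6.04, and Pearson correlations across the genes tested were 0.9947 to 0.9959 within groups and 0.9944 to 0.9960 between groups. The number of arrays, 3 per group, limits the precision of every comparison. Y-linked Eif2s3y, Uty and Kdm5d were present at similar levels on every array and Xist was low, with a mean of 3.98 in TG and a difference from WT of -0.03.

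The comparison asked how muscle transcript levels differed between the arrays labelled TG and those labelled WT. Socs3, the suppressor of cytokine signalling named in the series title, was measured at 7.15 ± 0.09 in TG and 7.41 ± 0.03 in WT on the log2 scale (SD, n = 3 each). The log2 difference, TG minus WT, was -0.26 (SE 0.07, 95% interval -0.42 to -0.09), and all 3 TG arrays lay below all 3 WT arrays. It did not pass the threshold over all genes (limma, adjusted p = 0.660). A second Socs3 probe set gave a difference of -0.22, with 6.14 ± 0.02 in TG and 6.37 ± 0.12 in WT (SD, n = 3 each). Whether either probe set lies in a part of the gene that the transgene carries is not given in the sources used here, so these values do not check the labels.

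Casp12, an inflammatory caspase family member, was the single gene past the threshold, and it was lower in TG. Its expression was 6.74 ± 0.15 in TG and 7.88 ± 0.05 in WT (SD, n = 3 each), a log2 difference of -1.14 (SE 0.09; limma, adjusted p = 0.0421), or 2.21-fold lower. The call ended when any 1 array was left out, with adjusted p from 0.0959 without TG array 3 to 0.471 without WT array 2, although the difference stayed between -1.20 and -1.06. It also ended with robust variance moderation (adjusted p = 0.0506), with arrays set to a common median (0.0628), with every probe set tested (0.547) and with liver transcripts as a covariate (0.194), the last of these added after seeing the data, over a range of 0.0025 to 0.547 across all alternatives. No gene was higher past the threshold, and the next smallest adjusted p was 0.221. At an unadjusted p under 0.05 there were 1346 genes, 391 higher and 955 lower, where 997 are expected by chance. The other 9 splits of the 6 arrays into 3 and 3 gave 656 to 1426 such genes, the highest with TG arrays 1 and 2 and WT array 1 on 1 side. The TG and WT values did not overlap for 2449 genes, or 12.3%, against 10% by chance.

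Among the genes with the smallest p that did not pass, those with lower values in TG included Socs2, a suppressor of growth hormone signalling, at 6.79 ± 0.15 in TG and 7.94 ± 0.31 in WT (SD, n = 3 each), a log2 difference of -1.15 (SE 0.16; limma, adjusted p = 0.299). The second Socs2 probe set gave a smaller difference, -0.38, and where in the genome each of the 2 probe sets lies was not determined here. Slc25a3, the mitochondrial phosphate carrier, differed by -0.56 (SE 0.07), the serine protease genes Htra4 and Prss29 by -0.81 and -0.56, Trim72, which encodes the membrane repair protein MG53, by -0.48, and the exocyst gene Exoc7 by -0.36. Gm4871, Zfp991 and Gm11541 differed by -0.74, -0.61 and -0.44. Of the genes with higher values in TG, Apaf1, the scaffold of the apoptosome, had the largest difference, 1.01 (SE 0.12), with 7.39 ± 0.17 in TG and 6.39 ± 0.19 in WT (SD, n = 3 each; limma, adjusted p = 0.221). 6720489N17Rik differed by 0.93, the dynein heavy chain gene Dnah7a by 0.67, Adipoq, which encodes the fat cell hormone adiponectin, by 0.64, the macrophage integrin gene Itgam by 0.57, Scyl2 by 0.56, the odorant receptor gene Olfr1331 by 0.54, Pdp2, a pyruvate dehydrogenase phosphatase, by 0.54, Utp20 by 0.52 and Chpt1, a choline phosphotransferase, by 0.50. With an intensity trend in the variance model, 7 genes passed, 2 higher and 5 lower, namely Casp12, Apaf1, Chpt1, Htra4, Slc25a3, Socs2 and Trim72. Apaf1, Slc25a3, Utp20, Chpt1 and Scyl2 lie in a run of 30 neighbouring genes on chromosome 10, described with its values further on.

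**Figure D1:**
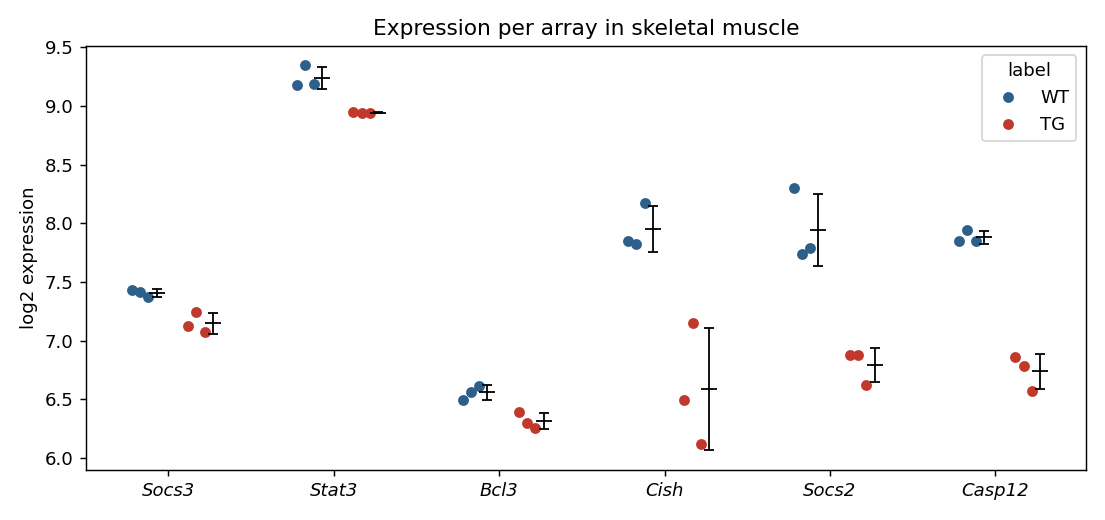
Log2 expression (vertical axis) of 6 genes on each array, with WT in blue and TG in red; bars give the mean and SD of the 3 arrays beside them. Stat3 and Bcl3 are the 2 members with the smallest p of the STAT3 list, and Cish and Socs2 those of the STAT5 list. In these lists 10 of 18 and 3 of 9 values were above 0. The TG arrays lie below the WT arrays for each of the 6 genes, with differences from -0.24 for Bcl3 to -1.37 for Cish. Groups did not overlap for 12.3% of all genes tested, and of these 6 genes Casp12 alone passed the threshold over all genes.

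Gene groups were compared through 40 lists fixed before the data were examined, of which 38 had enough measured members to be tested. With camera at its preset correlation, 8 lists passed an adjusted p of 0.05, 7 with higher and 1 with lower values in TG. With an estimated correlation none of the 38 passed, the smallest adjusted p was 0.777, and 1 list had an unadjusted p under 0.05. Fry called none either, with a smallest adjusted p of 0.0909 and 2 lists at an unadjusted p under 0.05. No list member passed over all genes tested. Adjusted over the list alone, 7 genes in 6 lists passed, as given with each list, and every other list had 0. The median difference over all genes was -0.016, and it was 0.003 with arrays set to a common median.

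The lists of fatty acid oxidation, the tricarboxylic acid cycle and oxidative phosphorylation were called with higher values in TG at the preset correlation, by small amounts, and not with an estimated correlation or fry. In the list of fatty acid uptake and oxidation, 24 of 30 measured genes had values above 0, with a median log2 difference of 0.053 (camera, adjusted p = 0.0020; adjusted p = 0.777 with an estimated correlation). Its members with the smallest p were the uncoupling protein gene Ucp3 at 0.21 (SE 0.07), the carnitine carrier gene Slc25a20 at 0.18 (SE 0.06), the lipoprotein lipase inhibitor gene Angptl4 at 0.27 and the thioesterase gene Acot2 at 0.29. This call held without each array in turn, at adjusted p from 0.0028 to 0.0177. The tricarboxylic acid cycle list had 18 of 21 genes above 0, with a median of 0.052 (adjusted p = 0.0133; adjusted p = 0.780 with an estimated correlation). Pdk4, the pyruvate dehydrogenase kinase, stood at 0.16 (SE 0.08), Mdh1 at 0.10, Dld at 0.12 and Dlst at 0.09. The cycle list shares 1 gene, Pdk4, with the fatty acid list and 2 genes with the oxidative phosphorylation list, so these calls are not fully separate. The oxidative phosphorylation list had 28 of 39 genes above 0, with a median of 0.024 (adjusted p = 0.0281; adjusted p = 0.780 with an estimated correlation), and its leading members were Ndufb3 at 0.17 (SE 0.08), Ndufs4 at 0.11, Ndufa1 at 0.16 and Uqcrfs1 at 0.11. The adjusted p of the cycle and phosphorylation lists rose to 0.0573 and 0.107 without TG array 1, to 0.0786 and 0.120 without TG array 2, to 0.163 and 0.413 without WT array 2, and to 0.0624 and 0.156 among the genes above the median level. Their mean differences, 0.044 and 0.029 over all arrays, were 0.041 and 0.026 without TG array 1, 0.044 and 0.027 without TG array 2, and 0.022 and 0.0043 without WT array 2.

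Glycolysis and glycogen genes were not called (7 of 22 above 0, median -0.020, adjusted p = 0.938), with Gbe1 at 0.13 and Ldha at -0.09. Lipid and cholesterol synthesis genes were not called either (12 of 21 above 0, median 0.014, adjusted p = 0.342). Among them the desaturase gene Scd1 was at 8.58 ± 0.21 in TG and 8.04 ± 0.07 in WT (SD, n = 3 each), a difference of 0.54 (SE 0.11), and passed when adjusted over the list alone (limma, adjusted p = 0.0307), while Srebf1, which encodes the lipogenic transcription factor SREBP-1, was at -0.38 (SE 0.10). Insulin signalling genes had 11 of 23 values above 0 and a median of -0.002 (adjusted p = 0.360), with the Rab GTPase-activating protein gene Tbc1d1 at 0.35 (SE 0.10) and Grb10 at 0.15.

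The cytokine and growth hormone pathways that SOCS proteins act on gave mixed values. In the list of growth hormone and STAT5-responsive genes, 6 of 9 genes were below 0, with a median of -0.074 (camera, adjusted p = 0.0528). Cish, a STAT5 target of the SOCS family, was at 6.58 ± 0.52 in TG and 7.95 ± 0.20 in WT (SD, n = 3 each), a difference of -1.37 (SE 0.24), or 2.58-fold. Cish and Socs2 passed when adjusted over the list alone (limma, adjusted p = 0.0027 and 9.5e-04), both lower, and neither over all genes. The Socs2 value comes from the probe set at -1.15, and its other probe set, at -0.38, was not tested within the list. The list passed with quantile normalization (adjusted p = 0.0252), with a common median (0.0415), among genes above the median level (0.0148), with a liver covariate (0.0216), without TG array 1 (0.0407) and without WT array 3 (0.0344). It did not pass without Socs2 as a member (0.315, added after seeing the data), with ranks of the statistic (0.291), with fry (0.0909), with an estimated correlation (0.777) or without each of the other 4 arrays (0.0551 to 0.141). The Socs2 gene lies on chromosome 10, as the 52nd tested gene counted from the start of the run of neighbouring genes, whose last gene is the 30th, but the probe set behind its value was not placed. STAT3-responsive genes had 10 of 18 values above 0 and a median of 0.014 (adjusted p = 0.938). Stat3 itself was at 8.94 ± 0.01 in TG and 9.24 ± 0.09 in WT (SD, n = 3 each), a difference of -0.30 (SE 0.07), and its target Bcl3 was at -0.24 (SE 0.07). Interferon-stimulated genes had 18 of 24 values below 0 and a median of -0.12 (adjusted p = 0.0528), with the interferon-induced GTPase gene Iigp1 at -0.72 (SE 0.13), which passed when adjusted over the list alone (limma, adjusted p = 0.0151), and Oas1a at 0.64 (SE 0.18). This list passed among genes above the median level (2.5e-05), without TG array 1 (0.0104), without WT array 3 (0.0050) and with the liver covariate (0.0216). These were 4 of 14 alternatives. It did not pass with an estimated correlation (adjusted p = 0.780), with fry (0.562) or without each of the other 4 arrays (up to 0.737). Cytokine and NF-kappaB genes had 10 of 20 values on either side of 0 (median -0.005, adjusted p = 0.628), with the chemokine genes Ccl7 at 0.28 and Ccl8 at -0.36.

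The macrophage, extracellular matrix and adipocyte lists were called with higher values in TG at the preset correlation, and not with an estimated correlation or fry. Macrophage markers had 16 of 19 genes above 0 and a median of 0.10 (camera, adjusted p = 0.0020; adjusted p = 0.780 with an estimated correlation). Itgam was at 5.64 ± 0.12 in TG and 5.06 ± 0.16 in WT (SD, n = 3 each) and passed when adjusted over the list alone (limma, adjusted p = 0.0121), while Ccr2, Lyve1 and Tyrobp were at 0.56 (SE 0.20), 0.33 and 0.26. Extracellular matrix genes had 25 of 30 values above 0 and a median of 0.076 (adjusted p = 0.0039; adjusted p = 0.780 with an estimated correlation), led by Mmp2 at 0.22 (SE 0.09), Col3a1 at 0.28, Col5a2 at 0.19 and Timp1 at 0.30. Adipocyte markers had 11 of 17 values above 0 and a median of 0.059 (adjusted p = 0.0133; adjusted p = 0.777 with an estimated correlation), with Adipoq at 5.92 ± 0.16 in TG and 5.29 ± 0.05 in WT (SD, n = 3 each), which passed when adjusted over the list alone (limma, adjusted p = 0.0031), and Lep, Plin1 and Retn at 0.26, 0.21 and 0.16. On TG array 1 the bone and osteoclast transcripts Mmp13, Ibsp, Acp5 and Ctsk, looked at after the data were seen, stood at 8.59, 7.36, 7.41 and 7.67, their highest level over the 6 arrays. Sp7, Alpl, Phex, Mmp9 and Sfrp4 also had their highest level there, while Omd, Dmp1, Sost, Oscar, Atp6v0d2, Ocstamp and Col11a2 did not. Acp5 and Ctsk were higher on each of the 3 TG arrays than on every WT array, with differences of 0.69 (SE 0.21) and 0.57 (SE 0.18), and neither passed over all genes. Of the 16 bone and osteoclast transcripts measured, Ocstamp and Col11a2 were lower on each TG array than on every WT array, at -0.20 and -0.17.

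The calls of these 3 lists ended without some of the arrays, each time with fewer arrays in the test. The macrophage call ended without TG array 2 (adjusted p = 0.0757) and without WT array 3 (0.363). That of the matrix list ended without TG array 1 (0.249), TG array 2 (0.185) and WT array 1 (0.0506), and that of the adipocyte list without TG array 2 (0.134) and WT array 1 (0.126). The mean difference of the macrophage list went from 0.16 to 0.11 without TG array 2 and 0.073 without WT array 3, that of the matrix list from 0.096 to 0.035 without TG array 1, 0.053 without TG array 2 and 0.077 without WT array 1, and that of the adipocyte list from 0.089 to 0.061 without TG array 2 and 0.066 without WT array 1. Among genes above the median level the adjusted p reached 0.128, 0.0960 and 0.234.

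Other cell types were not called. Fibroblast markers had 10 of 13 values above 0 (median 0.076, adjusted p = 0.0528), with Pi16 at -0.28 and Pdgfra at 0.16. The fibroblast list passed without TG array 3 (adjusted p = 4.9e-04), without WT array 1 (0.0482) and with the liver covariate (0.0069). Lymphocyte markers had 9 of 14 values below 0 (median -0.099, adjusted p = 0.136), with the T cell genes Cd3g and Cd8a at -0.30 and -0.24. Neutrophil and mast cell markers had 7 of 12 values above 0 (median 0.004, adjusted p = 0.851), with Ngp at 0.19 and S100a8 at -0.29. Endothelial markers had 10 of 15 values below 0 (median -0.042, adjusted p = 0.521), with Egfl7 at -0.25 and Pecam1 at 0.14. Smooth muscle and pericyte markers had 8 of 12 values below 0 (median -0.042, adjusted p = 0.973), with Myh11 at 0.16 and Notch3 at -0.08. Schwann cell and nerve markers had 10 of 13 values below 0 (median -0.086, adjusted p = 0.393), with Ngfr at -0.17 and Nefm at 0.18. Tendon and cartilage markers had 9 of 12 values below 0 (median -0.12, adjusted p = 0.131), and the tendon transcription factor gene Mkx, at -0.35 (SE 0.07), passed when adjusted over the list alone (limma, adjusted p = 0.0184), with Comp at -0.23. The tendon list passed without WT array 3 (6.5e-04). Keratinocyte and skin markers had 8 of 10 values below 0 (median -0.14, adjusted p = 0.384), with Krt5 and Krt15 at -0.31 and -0.15. Satellite cell markers had 7 of 12 values below 0 (median -0.007, adjusted p = 0.938), with the myogenic factor gene Myod1 at -0.48 (SE 0.17) and Cdh15 at -0.10. Neuromuscular junction genes had 10 of 14 values below 0 (median -0.070, adjusted p = 0.125), with Musk, the agrin receptor kinase gene, at -0.24 and Etv5 at -0.20. Of the erythroid markers 4 were measured and the list was not tested, with Epb42 at -0.34 and Alas2 at 0.15. The sex-linked list, also not tested, had Eif2s3y at 0.14 and Uty at 0.12.

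Immediate early genes, which are induced within minutes of a stimulus, were the single list called with lower values in TG. Of 20 genes, 15 were below 0, with a median of -0.25 (camera, adjusted p = 0.0079; adjusted p = 0.780 with an estimated correlation). The phosphatase gene Dusp1 was at 10.9 ± 0.17 in TG and 11.7 ± 0.39 in WT (SD, n = 3 each), a difference of -0.81 (SE 0.19), and Egr3, Nr4a1 and Klf2 were at -0.39, -0.44 and -0.47. The call ended without TG array 3 (adjusted p = 0.169), without WT array 2 (0.441) and with a liver covariate (0.148), and the mean difference, -0.22 over all arrays, was -0.16 without TG array 3 and -0.042 without WT array 2. Heat shock genes had 13 of 15 values above 0 and a median of 0.098 (adjusted p = 0.0281; adjusted p = 0.780 with an estimated correlation). Hspa1a was at 8.21 ± 0.98 in TG and 7.56 ± 0.30 in WT (SD, n = 3 each), with its highest level, 9.25, on TG array 2 and its lowest, 7.30, on TG array 3. Hsp90aa1 was at 0.41 (SE 0.32), Hspa4l at 0.19 and Dnajb1 at -0.18. The heat shock call ended without TG array 1 (adjusted p = 0.0799), TG array 2 (0.831), WT array 1 (0.214) and WT array 2 (0.0915), and among genes above the median level (0.128), while the mean difference, 0.14 over all arrays, was 0.15 without TG array 1, 0.013 without TG array 2, 0.097 without WT array 1 and 0.12 without WT array 2. Alb, the liver albumin gene, also had its highest level, 10.7, on TG array 2 and its lowest, 6.28, on TG array 3. With the liver covariate the heat shock call was kept.

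Other stress and rhythm lists were not called. Unfolded protein response genes had 13 of 22 values above 0 (median 0.010, adjusted p = 0.555), with Dnajb9 at 0.25 and Trib3 at -0.21. Antioxidant and NRF2 genes had 12 of 20 values above 0 (median 0.031, adjusted p = 0.277), with the heme oxygenase gene Hmox1 at 0.59 (SE 0.23) and Gpx3 at -0.47 (SE 0.15). Circadian clock genes had 12 of 16 values below 0 (median -0.043, adjusted p = 0.393), with Bhlhe40 at -0.48 and Nr1d1 at -0.18, and passed with the liver covariate (0.0203).

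No list of contractile genes, fibre type or muscle protein turnover was called. Slow fibre genes had 13 of 18 values below 0 (median -0.026, adjusted p = 0.628), with the calcineurin-binding Z-disc gene Myoz2 at -0.52 (SE 0.19) and the slow troponin gene Tnnt1 at -0.21. Fast fibre genes had 14 of 18 values below 0 (median -0.019, adjusted p = 0.807), with the myosin kinase gene Mylk2 at -0.22 and Myh2 at -0.30. Calcium handling genes had 19 of 28 values below 0 (median -0.018, adjusted p = 0.973), with Pln at 0.21 and Cacna2d1 at 0.11. The calcineurin, NFAT and MEF2 list, which shares Myoz2, had 12 of 21 values above 0 (median 0.023, adjusted p = 0.672), with Camk2a at -0.09. Sarcomere, costamere and dystrophin complex genes had 14 of 27 values below 0 (median -0.005, adjusted p = 0.384), with Cav3 at -0.17 and Dmd at 0.12. Denervation and regeneration genes, which include Myod1 and Musk, had 13 of 24 values below 0 (median -0.006, adjusted p = 0.986). Atrophy and proteolysis genes had 14 of 25 values above 0 (median 0.014, adjusted p = 0.315), with Gadd45a at 0.27 and Map1lc3a at 0.16. Proteasome genes had 17 of 31 values above 0 (median 0.015, adjusted p = 0.138), with Psma1 at 0.14 and Psma5 at 0.13. Cytosolic ribosomal protein genes had 28 of 32 values below 0 (median -0.034, adjusted p = 0.314), with Rpl27 at -0.12 and Rps20 at -0.11, and cell cycle genes had 13 of 21 below 0 (median -0.020, adjusted p = 0.858), with Cdk1 at -0.39 and Mcm3 at 0.16. The ribosomal and neuromuscular junction lists passed among genes above the median level (adjusted p = 0.0148 and 0.0296), the proteasome list without TG array 1 (0.0339) and the atrophy list without WT array 2 (0.0018). In 8 lists the median, the mean and the test differed in sign, and these were the insulin, sarcomere, cytokine, calcineurin, neutrophil and mast cell, glycolysis, STAT3 and denervation lists.

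**Figure D2:**
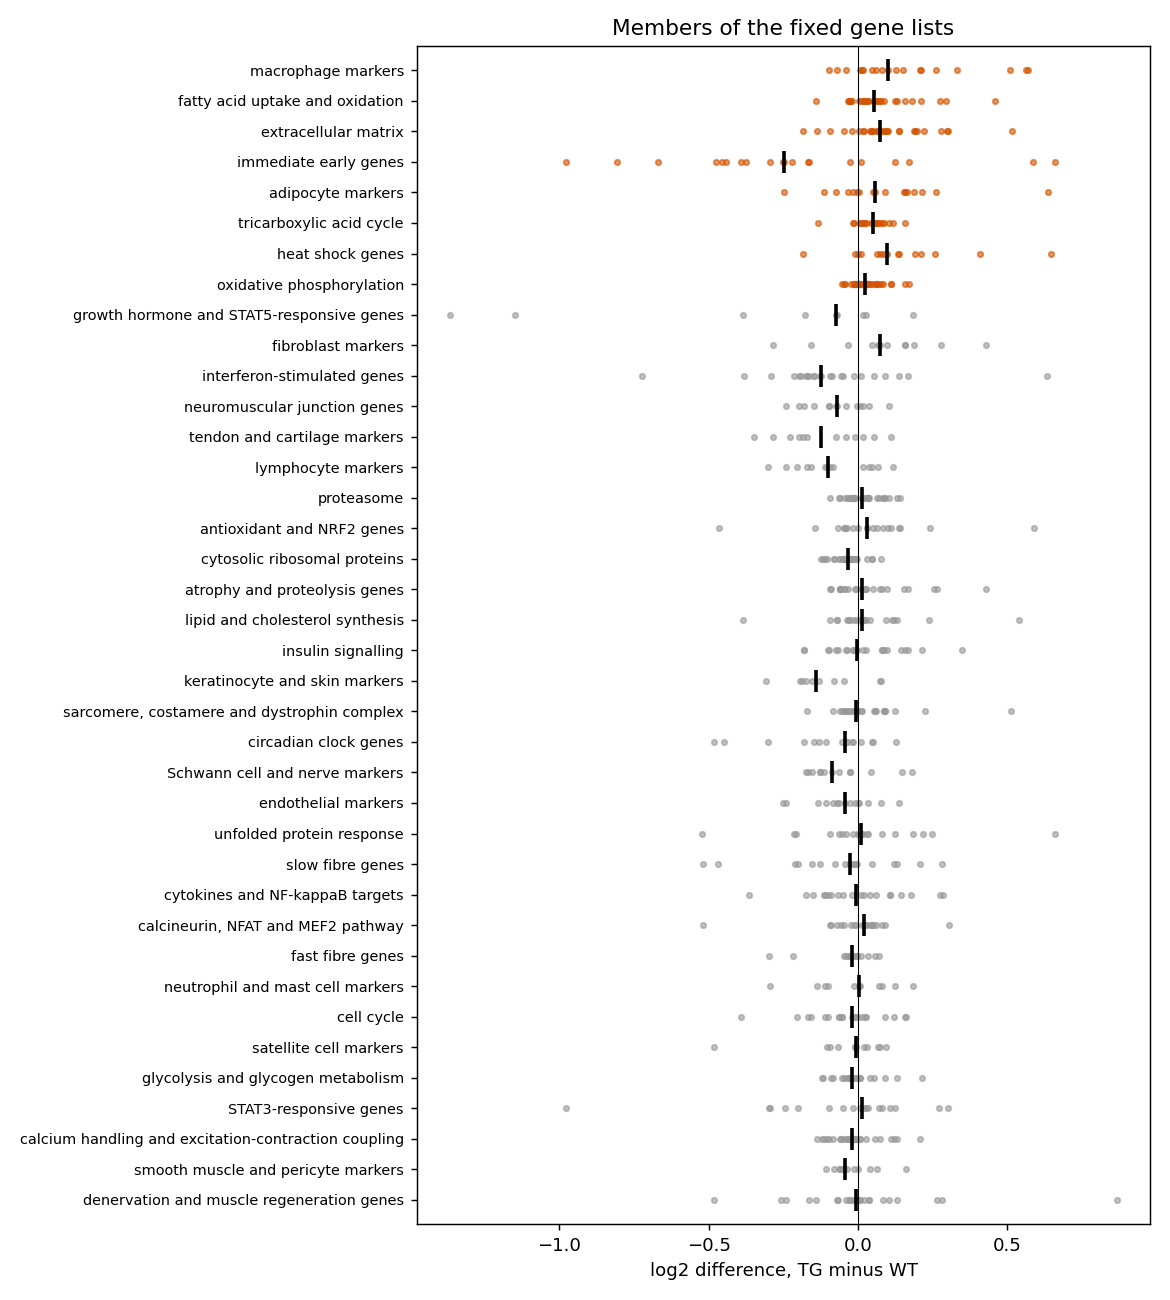
Log2 difference, TG minus WT (horizontal axis), of each measured member of the 38 tested lists (points, 1 list per line, ordered by p), with the list median as a black bar; the 8 lists called with the preset correlation are orange. Medians of the called lists lie between -0.25 for immediate early genes and 0.10 for macrophage markers.

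Genes with small p-values lay close together on chromosome 10, in the gene order of mouse assembly GRCm38.p6. In the fullest run of 30 neighbouring tested genes, 14 had an unadjusted p under 0.01, or 46.7%. The share was 1.30% on the chromosome outside the run and the 30 genes on either side of it (11 of 849 genes). On the other chromosomes it was 1.38%. Of the 14 genes, 9 were higher in TG, namely Apaf1, Scyl2, Utp20, Uhrf1bp1l, Chpt1, Actr6, Gnptab, Washc3 and the slow myosin-binding protein gene Mybpc1, and 5 were lower, namely Slc25a3, Ikbip, Ano4, Nedd1 and Gm6653. Mybpc1 was at 13.3 ± 0.01 in TG and 13.1 ± 0.03 in WT (SD, n = 3 each), a difference of 0.26 (SE 0.06). The 30 genes before the run held 0 such genes, and the 30 after it held 2, Mir331 at -0.31 and Socs2, which counts through the probe set at -1.15, not placed here; its other probe set, at -0.38, had an unadjusted p of 0.0156 and would not count. The fullest run elsewhere in the genome held 4. With an array left out, the fullest run anywhere in the genome held 8 without WT array 1 and 9 without TG array 1, and its place was not recorded.

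**Figure D3:**
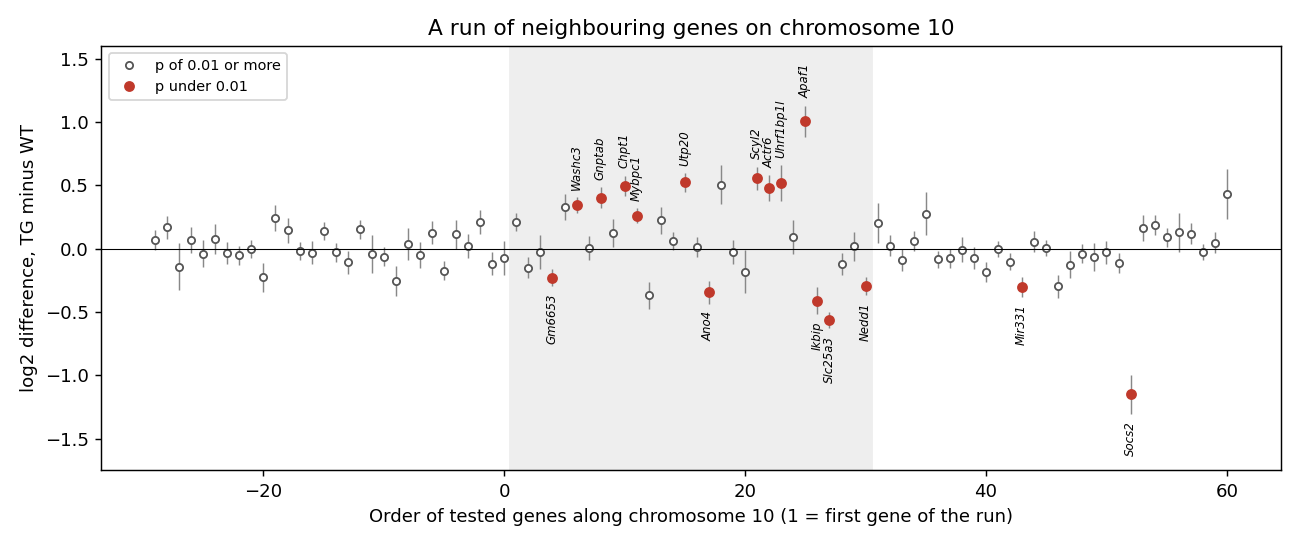
Log2 difference, TG minus WT, with its standard error (vertical axis), of tested genes in their order along chromosome 10 (horizontal axis), from 30 genes before the run to 30 after it, with the run of 30 shaded; filled red points are genes with an unadjusted p under 0.01. Inside the shading 14 of 30 genes are red, 9 above and 5 below 0, and Socs2, drawn at the place of its gene, is at -1.15 from a probe set that was not itself placed, while its other probe set gave -0.38.

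Transcripts of liver varied between arrays by more than the groups differed. Alb was measured at 8.70, 10.7 and 6.28 on the 3 TG arrays and at 8.99, 9.48 and 10.2 on the 3 WT arrays, so the TG arrays spanned 4.39 on the log2 scale, or 20.9-fold. Serpina1c spanned 19.1-fold within TG, with a group difference of -1.13 (SE 0.91; limma, adjusted p = 0.826), and Ahsg spanned 12.6-fold, with a difference of -1.05 (SE 0.80). The list of 15 liver transcripts was drawn up after their values were seen.

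**Figure D4:**
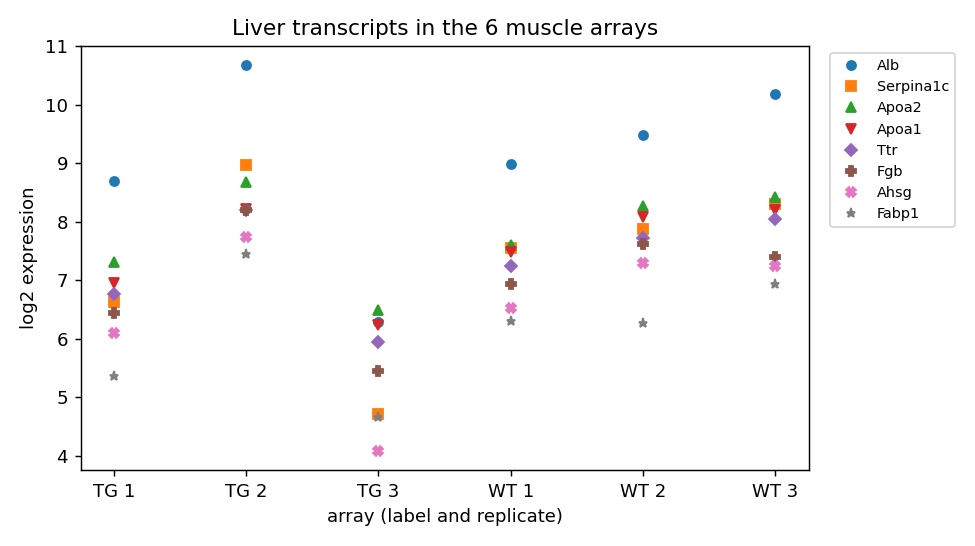
Log2 expression (vertical axis) of 8 liver transcripts on each of the 6 arrays (horizontal axis, label and replicate), 1 marker shape per gene. All 8 are highest on TG array 2 and lowest on TG array 3, where Alb is at 6.28.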

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

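The liver covariate, the STAT5 list without Socs2 and the changes to the scan of neighbouring genes were chosen after the data were seen. The count of 1 gene, lower in TG, was the same with array weights, the mean of probe sets and quantile normalization. It became 7 with an intensity trend (2 higher, 5 lower), 2 among genes above the median level (both lower, Casp12 and Slc25a3), and 0 with robust moderation, with every probe set tested, with a common array median and with the liver covariate. The count was 0 to 0 without each array in turn. The rule of unadjusted p under 0.01 with a 1.5-fold change gave 31 genes, 9 higher and 22 lower. The leave-outs use fewer arrays by construction, and for the other losses the cause was not tested. The Socs3 difference stayed between -0.31 and -0.22 and never passed. Over the 110 other named genes and all alternatives, 1603 of 1620 values kept their direction and side of the threshold, 10 lost the threshold, 7 gained it and 0 reversed. All 10 losses were of Casp12, since no other named gene had a call to lose, so the high share that stayed does not speak for that call. Called lists numbered 8 with the preset correlation, with ranks and without Socs2 in the STAT5 list, 9 with quantile normalization and with a common median, 6 among genes above the median level, 11 with the liver covariate, 0 with an estimated correlation and 0 with fry. They numbered 2 to 10 without each array in turn, with 2 without TG array 2 and 5 without WT array 2. Over all lists, called or not, 468 results stayed on their side of the threshold, 42 lost a call and 19 gained one. The fullest run anywhere in the genome, whose place was not recorded, held 11 genes in runs of 20 and 16 in runs of 50. It held 13 genes with quantile normalization and 14 with the liver covariate. Without each array in turn it held 8 to 12, the lowest without WT array 1, with 9 without TG array 1. Whether these runs lay on chromosome 10 was not checked. The covariate from Y-linked genes was not run, because their mean differed by 0.141 over the arrays, under the limit of 1 fixed for it. Signal over background could not be assessed from the deposited values, so no limit can be given for dim genes.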

Other observations

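All tests in this part except the splits of the arrays for the count of genes and for the count of lists were chosen after the result was seen. Of 16 measured bone and osteoclast transcripts, 10 had values above 0 in TG, with a median log2 difference of 0.09, and none passed over all genes. Acp5 and Ctsk, the acid phosphatase and collagenase of osteoclasts, were the 2 genes higher on every TG array than on every WT array, while 2 others were lower on every TG array, and the collagenase gene Mmp13 was at 8.59 on TG array 1 against 5.89 to 6.99 on the other 5 arrays. Nnt, the nicotinamide nucleotide transhydrogenase gene that carries a deletion in the C57BL/6J strain, was at 9.55, 8.18 and 8.36 on the TG arrays and at 9.75, 9.53 and 8.54 on the WT arrays. It was chosen after its values were seen. The 15619 probe sets outside the genes tested held 0 past an adjusted p of 0.05 (limma) and 895 with an unadjusted p under 0.05, where 781 are expected by chance.

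The count of 1 gene past the threshold was reached in 1 of the 10 splits of the 6 arrays, the real one, and the highest other split gave 0. With 10 splits no share under 0.05 can be had.

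The first pattern is the run on chromosome 10, where 14 of 30 neighbouring genes had an unadjusted p under 0.01. The tables argue against chance position, since 10000 random placements of the same p-values gave at most 7 (permutation p = 1e-04, the smallest they can give). They also argue against array scaling or liver RNA. The fullest run in the genome, its place not recorded, still held 13 genes at the lower of the counts with quantile normalization and with the liver covariate. A candidate explanation is a chromosome segment that differs between the groups, such as DNA inherited along with a transgene or from another strain. It stays open: the share on the chromosome outside the run and the 30 genes on either side was 1.30%, but since the run was chosen as the fullest, a low share outside it adds nothing for a segment. Neither the place of the transgene nor sequence differences under probes were tested. The real split gave 14 and the highest of the other 9 splits gave 5, with 1 of 10 splits as large, too few for a share under 0.05.

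The second pattern is the liver transcripts. RNA from liver tissue is a candidate source: all 18 measured liver genes not looked at before were higher on TG array 2 than on TG array 3, with a median difference of 0.90 on the log2 scale, or 1.87-fold, against at most 0.167 for 10000 random lists of the same size and level. The same value argues against the transgene alone, since both arrays carry the TG label. A group difference on top of it stays open. In TG, 14 of the 15 genes first noticed and 16 of the 18 others were below 0 (median -0.68 and -0.27). Camera at the preset correlation gave these lists an unadjusted p of 0.0065 and 0.0135. That test takes the members as nearly independent, yet the liver genes rose and fell together over the arrays. In both lists, 0 genes had an unadjusted p under 0.05 (limma). Alb spanned 4.39 on the log2 scale within TG. These values show that liver genes moved together over the arrays, and not where their RNA came from. If liver tissue was the source, whether its RNA entered at dissection or later was not tested.

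The third pattern is the set of 8 list calls, of which the 7 lists other than fatty acid uptake and oxidation lost the call without some array, and 6 of them then also lost over 50% of their mean difference. At the lowest, 9.18% was kept for heat shock, 14.4% for oxidative phosphorylation, 19.3% for immediate early, 36.7% for extracellular matrix, 45.0% for macrophage and 49.8% for tricarboxylic acid cycle genes, against 69.2% for the adipocyte list, so single arrays may carry part of these calls, while the fatty acid list kept its call, with a highest adjusted p of 0.0177. Its call too was lost with an estimated correlation (camera, adjusted p = 0.777) and with fry (adjusted p = 0.117). Without TG array 1 the macrophage list kept its call (camera, adjusted p = 0.0239) and 79.3% of its mean difference. The difference left cannot come from bone tissue in TG array 1. The call decides nothing further, since every regrouping of the arrays gave list calls too. Bone tissue in TG array 1 stays open for the extracellular matrix list, which lost its call without that array (0.249). Bone tissue in all TG arrays stays open for both lists. Of 16 bone and osteoclast genes, 2, Acp5 and Ctsk, were higher on every TG array, and 2 others were lower on every TG array. Over all genes, 12.3% had groups that did not overlap, so these few genes do not decide it. The real split gave 8 lists and the highest other split gave 8 as well, so 2 of the 10 splits were as large, the other being TG arrays 1 and 2 with WT array 2 against the rest, and 10 splits are too few for a share under 0.05, so an effect of the transgene on these lists stays open.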
